A study of Mus musculus with 2 samples.

How the data were processed

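The series holds 2 MeDIP-seq libraries of mouse ES cells with a tet-regulated Zscan4c transgene, 1 with the transgene repressed by doxycycline and 1 with it induced by leaving the drug out. Per the labels' protocols, genomic DNA was sonicated to fragments of 300 to 1000 bp, denatured, precipitated with an antibody against 5mC, and sequenced on an Illumina Genome Analyzer II. Per the submitters' processing notes the genome build is mm9. The aligner, the counting tool, the treatment of duplicate reads and the way the regions were chosen are not given in the sources used here. No input or control library was analysed here.

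The deposited table gives for each of 23946 regions a position, a whole-number count in each library and an adjusted value in each library. The counts deposited by the authors are raw and not normalized. The adjusted signal deposited by the authors was found to be the count times 1 factor per library, rounded to 1 decimal. A factor of 1.19 for the induced and 0.863 for the repressed library, each the mean of both totals divided by the library's own total over the 23932 regions with an adjusted value, gave all deposited adjusted values to within 0.051. The adjusted cells are blank for the 14 regions with the highest counts. This scaling sets the totals of the libraries equal, so it removes any change that all regions share. Starts and ends are printed as the file gives them. The file does not state whether starts count from 0 or 1, so a start may be off by 1 bp. Of the regions, 527 overlap the one before, and reads in an overlap may be counted in both.

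Ratios were computed from the counts times the unrounded factors. The log2 ratio of induced over repressed used a pseudocount of 1, which shrinks the ratios of regions with few counts. Ratios of counts carry 95% exact Clopper-Pearson binomial intervals. With 1 library per group there are 0 residual degrees of freedom, so edgeR's test across replicates could not be fitted, and no p-value for the conditions is given. The exact two-sided binomial test compares each region's counts with the share of 42.1% that the induced library had over all scaled regions, with Benjamini-Hochberg adjustment over the regions with a count and a threshold of 0.05. It asks whether 2 libraries differ by more than counting error. A beta-binomial test added a spread shared by all regions, fitted by moments to the regions with a summed count of at least 10 other than those called (fitted spread 0.0133), and 100 simulations drew counts with that spread and no other difference. Chance splits divided each region's summed count at random with the same share, 1000 times for counts of regions, 100 times for correlations and for counts at an unadjusted p under 0.05, and 200 times for regions without a count.

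Before the data were examined, the position classes, the pseudocount, the 2-fold threshold and the rule for named regions were fixed: the 12 largest decreases and 12 largest increases in log2 ratio among regions with a mean signal at or above the median and a summed count of at least 20. The binomial and beta-binomial tests, the classes by summed count and by length and the 1 Mb windows were chosen after seeing the data. The fixed gene lists (among them 2-cell embryo, imprinted, germline, pluripotency, heterochromatin and telomere genes) and the comparison of promoters, gene bodies and intergenic regions were not run, because the table gives no gene names and the gene table at hand is of assembly GRCm38, whose coordinates differ from mm9. Regions are therefore named by the identifier in the table and their mm9 position, with no gene, exon or intron assigned. Chromosome ends were taken as the outermost listed region of each chromosome.

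Alternatives covered the pseudocount, scaling by edgeR's TMM and by DESeq2's median of ratios, no scaling, filters on low signal, the fold threshold and the distance to the chromosome end. In log2 units the scaling factor moved by −0.07 under TMM, by −0.27 under the median of ratios and by −0.46 without scaling.

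The tests were tried on simulated data with 200 changed regions among 23932, all with a summed count of at least 20 in the real data. The binomial test recovered 2.5% of 2-fold increases, 27.5% of 4-fold and 90.0% of 8-fold increases, 32.5% of decreases to 0.25 times and 2.5% of decreases to 0.5 times, and called 1 unchanged region. With the fitted spread in the simulated counts, the beta-binomial test recovered 0% of 2-fold, 7.5% of 4-fold and 55.0% of 8-fold increases. A spread of 0.02 put into simulated counts was estimated as 0.0249. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.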

Results

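DNA methylation was profiled by methylated DNA immunoprecipitation followed by sequencing (MeDIP-seq) in mouse embryonic stem (ES) cells that carry a doxycycline-regulated Zscan4c transgene. Zscan4 genes encode SCAN-domain zinc-finger proteins that are transcribed in the 2-cell embryo and, transiently, in a small share of ES cells. The transgene works in the tet-off configuration. It was silent in the library made with 1.5 µg/ml doxycycline (Zscan4 repressed) and active in the library made without the drug (Zscan4 induced). In MeDIP an antibody against 5-methylcytosine (5mC) pulls down sheared single-stranded DNA, so the count of a region rises with the number of methylated cytosines it holds and with sequencing depth. The question was how DNA methylation differs between cells with and without Zscan4 induction. Each condition has 1 library, and every value below therefore compares these 2 libraries and carries no replicate check. The libraries differ in doxycycline as well as in Zscan4, so an effect of the drug itself cannot be told apart from that of the transgene. The parent line is of the 129S6/SvEvTac strain, and the cells were grown without feeders.

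The deposited table lists 23946 regions of the mm9 mouse genome on the 19 autosomes and chromosomes X and Y, covering 31.9 Mb in all. The regions are between 1000 and 7077 bp long, with a median of 1111 bp, and 10619 of them measure exactly 1000 bp. The counts over all listed regions sum to 51169 in the induced library and 70219 in the repressed library. Sampling was sparse: the median region held 1 count in the induced and 2 counts in the repressed library. No count was seen in 7247 regions of the induced library (30.3%) and in 4986 regions of the repressed library (20.8%), among the 23932 regions that the authors scaled. In a region with a summed count of 3, the median, split as 1 and 2, the 95% exact binomial interval of the induced-to-repressed ratio runs from 0.0117 to 13.2. A region with a summed count of 50 has an interval from 0.541 to 1.81. Intervals cover counting error only, and no variation between replicates. They may be too narrow even for counting error, since reads amplified by PCR without molecular identifiers are not independent molecules.

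Across the listed regions, slightly more held a lower than a higher 5mC signal in the induced library once both libraries were scaled to the same total. Of the 23932 regions, 10924 (45.6%) were lower in the induced library, 10385 (43.4%) were higher, and 2623 held no count in either. Splitting each region's counts between the libraries by chance alone gave 10733 lower regions (95% of splits between 10580 and 10879) and 10576 higher regions (10430 to 10728). Both observed numbers lay outside counting error, toward lower signal. This excess is not independent of a later result. With equal totals, the ratio of 1.09 at 20 or more counts puts the other regions, summed, below 1. Of the differing regions 51.3% were lower, but 42.5% at 20 or more counts. Filters on signal gave 45.9% and 45.7%, by construction. At a 2-fold threshold, 3724 regions (15.6%) were lower and 3763 (15.7%) were higher. The same chance splits gave 3491 lower regions (95% of splits between 3386 and 3591) and 3785 higher regions (3671 to 3888). At this threshold the number of higher regions lay within counting error, and the number of lower regions exceeded it. The near balance of the 2 numbers has no meaning by itself. With these factors and a pseudocount of 1, a single induced count passes the threshold and a single repressed count does not. The higher regions thus include all 1402 with 1 induced count alone, and the lower ones leave out the 2181 with 1 repressed count alone. The chance splits share this asymmetry. These 2-fold counts and their balance hang on the pseudocount and the scaling, and the chance splits cover the main setting alone. With a pseudocount of 10 there were 6 lower and 6 higher regions, with 0.1 there were 6890 and 5350, and without scaling 7537 and 3351. The log2 ratio, with a pseudocount of 1, had quartiles of −0.87 and 0.58. Its median was 0 under every scaling tried, including none, and therefore carries no information on a shift. The counts of the libraries correlated across regions with a Pearson r of 0.73 and a Spearman rho of 0.52, against 0.76 and 0.54 in the chance splits. Regions are not independent replicates, so no p-value is attached to these correlations.

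Before scaling, the listed regions held 0.726 times as many counts in the induced as in the repressed library. Without scaling, 66.3% of the regions that differed were lower in the induced library, against 51.3% with it. Library totals outside the listed regions were not used here, so a change of the same size in all regions cannot be separated from a difference in sequencing depth, and all ratios below are relative to the total of the scaled regions.

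**Figure D1:**
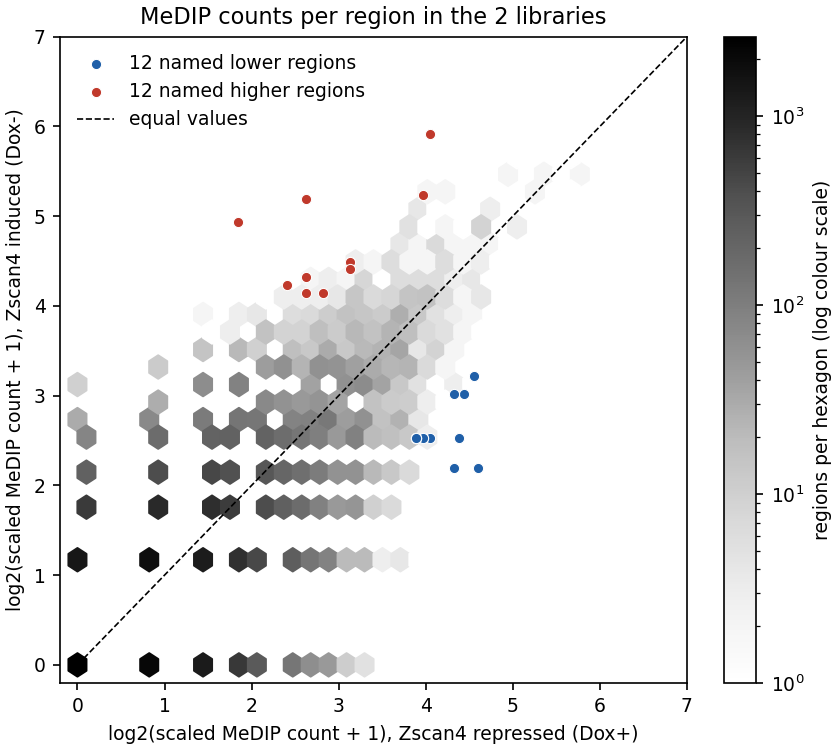
Each hexagon shows how many of the 23932 scaled regions have a given log2(scaled count + 1) in the repressed library (horizontal axis) and the induced library (vertical axis), without replicates. The named lower regions (blue) and named higher regions (red) are the 12 largest differences on each side at a summed count of at least 20. Some of them overlap in the plot. The dashed line marks equal values, and the log2 ratio of all scaled regions had quartiles of −0.87 and 0.58.

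Regions with 20 or more counts, in which a difference can be seen most clearly, held relatively more signal in the induced library. This class comprised 617 regions (2.58%), of which 355 were higher and 262 lower in the induced library. Their summed scaled counts gave an induced-to-repressed ratio of 1.09 (95% exact binomial interval 1.06 to 1.12). The ratio was 0.931 (0.895 to 0.967) in the 7207 regions with a summed count of 1 or 2, and 0.991 (0.977 to 1.004) in regions with 3 to 19 counts. In relative terms, the ratio of the regions with 20 or more counts was 1.17 times that of the regions with 1 or 2 (95% interval 1.12 to 1.23) and 1.10 times that of the regions with 3 to 19 (1.07 to 1.14), and these relative values do not depend on the scaling. The ratio of 1.09 itself does: it was 1.04 under TMM scaling, and it flipped to 0.904 under median-of-ratios scaling and 0.791 without scaling. The median of ratios uses only the 14322 regions with a count in both libraries. With so few counts per region it moves in coarse steps, and its factor was 1.14 against 1.38 from the totals. How far leaving out the other regions moves it was not tested, so the value of 0.904 is weak evidence of a reversal. The spread of the regions around the common share grew with the count as well. It was 0.984 times the binomial variance at 1 or 2 counts, 1.14 times at 10 to 19, 1.36 times at 20 to 49, and 2.71 times at 50 or more. Without the 3 regions called below, the last 2 values were 1.27 and 2.14 times. Simulated counts with an equal beta-binomial spread in every region rose with the count too, to 1.16, 1.35 and 1.94 times on average in the last 3 classes (95% of simulations between 1.25 and 2.83 in the last). That spread was fitted to these same 3 classes without the called regions, so the level of the simulated values is no check of it.

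**Figure D2:**
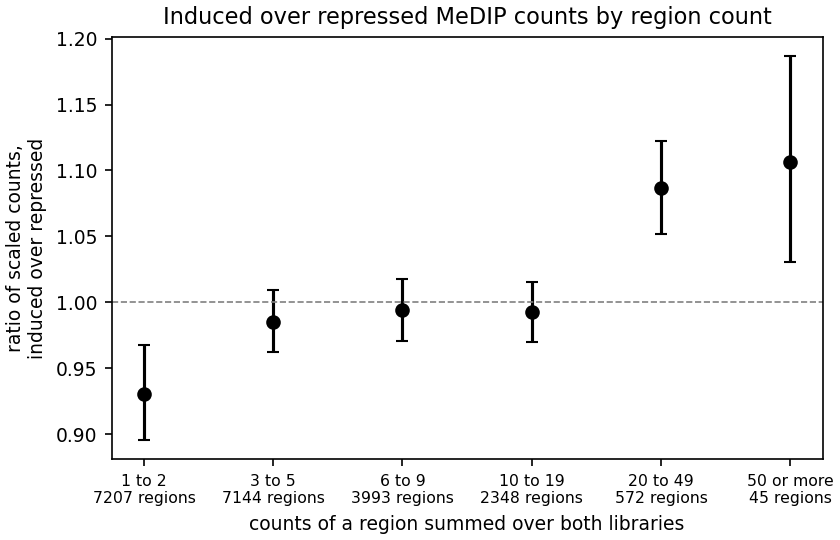
Induced-to-repressed ratio of summed scaled counts (vertical axis, not starting at 0) for regions grouped by their count summed over both libraries (horizontal axis), with 95% exact binomial intervals as bars. The ratio was 0.931 at 1 or 2 counts, close to 1 between 3 and 19 counts, and 1.09 at 20 to 49 counts.

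Of the single regions, 3 stood apart from counting error, all with more signal in the induced library. The region R18340 on chromosome 6 (87578588 to 87579588) held 25 counts in the induced and 3 in the repressed library, a scaled ratio of 11.5 (95% exact binomial interval 3.50 to 59.4). The region R05912 on chromosome 13 (59578764 to 59580015) held 30 and 6 counts, a ratio of 6.89 (2.82 to 20.2). The region R02755 on chromosome 11 (6312287 to 6313287) held 50 and 18 counts, a ratio of 3.83 (2.19 to 6.97). These were the 3 of 21309 regions with a count that passed an exact two-sided binomial test after Benjamini-Hochberg adjustment, each with an adjusted p = 0.00373. The test compares the reads of these 2 libraries, not the conditions. No region passed in the other direction. At an unadjusted p under 0.05 there were 287 higher and 183 lower regions, 470 in all, against 350 in chance splits (326 to 382). All 3 calls ended when the extra spread shared by all regions was allowed for in a beta-binomial test (adjusted p = 0.248, 0.288 and 0.913 in the order given), which called 0 regions and had 309 at an unadjusted p under 0.05. They also ended in the binomial test under median-of-ratios scaling (0 regions called, 471 at an unadjusted p under 0.05) and without scaling (0 called, 347). The ratios were then 9.52, 5.71 and 3.17 under the median of ratios and 8.33, 5.00 and 2.78 without scaling, in the same order, each with an interval above 1. The limit of the median of ratios at this depth, given above, holds here too. Under TMM scaling 3 regions passed the binomial test.

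The neighbours of the chromosome 11 region did not share its difference, and those of the other 2 regions held too few counts to show whether they do. The other scaled regions within 100 kb summed to 4 counts in the induced and 5 in the repressed library around the chromosome 6 region, a scaled ratio of 1.10 (0.219 to 5.12), to 5 and 4 around the chromosome 13 region, a ratio of 1.72 (0.371 to 8.67), and to 22 and 29 around the chromosome 11 region, a ratio of 1.04 (0.572 to 1.88). The last interval lies below that of the region itself (2.19 to 6.97), while the intervals around the other 2 overlap those of their regions.

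The other regions named by the rule on size gave the following picture. Among the higher ones, R19401 on chromosome 7 (31387019 to 31388777) held 15 induced and 5 repressed counts, a ratio of 4.13 (1.43 to 14.5). R11708 on chromosome 19 (61301941 to 61302941) and R15537 on chromosome 4 (120689269 to 120690993) each held 16 and 6 counts, a ratio of 3.67 (1.36 to 11.5). R15731 on chromosome 4 (131844177 to 131845177) was better covered, with 31 and 17 counts and a ratio of 2.51 (1.35 to 4.84). The remaining 5 higher regions, R12077, R04322, R09421, R17913 and R15813 on chromosomes 2, 11, 17, 6 and 4, had log2 ratios down to 1.27. These regions were picked for their size, so their intervals are no test. In chance splits the 12th highest log2 ratio was 1.11 on average (95% of splits between 0.967 and 1.25), against the 1.27 observed. The splits and the observed value both hold for the main scaling alone, and the splits include no extra spread.

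The lower regions were led by R17634 on chromosome 5 (144175168 to 144176874), with 3 counts in the induced and 27 in the repressed library, a ratio of 0.153 (0.0297 to 0.497). R13410 on chromosome 2 (174878723 to 174879855) held 3 and 22 counts, a ratio of 0.188 (0.0360 to 0.625). R20696 on chromosome 8 (20012565 to 20013565) held 4 and 23 counts, a ratio of 0.239 (0.0602 to 0.701). R14095 on chromosome 3 (89801687 to 89802687) held 4 and 18 counts, a ratio of 0.306 (0.0753 to 0.929). R13776 on chromosome 3 (41410044 to 41411815) and R05119 on chromosome 12 (92952136 to 92953752) had 6 and 24, and 7 and 26 counts. The remaining 6 were R09555 on chromosome 17, R20689 and R21722 on chromosome 8, R12222 on chromosome 2, R22901 on chromosome 9 and R18015 on chromosome 6, with log2 ratios up to −1.30. The 12th lowest value lay within the range of chance splits, which gave −1.23 on average (−1.40 to −1.09). Among the 617 regions with 20 or more counts, 30 were lower by 2-fold or more. Counting error alone gave 27.6 on average (95% of splits between 18 and 38). In the same class 43 were higher, where it gave 18.7 (11 to 27). These splits used the main scaling, the share of all regions and no extra spread. The summed ratio of this class was 1.09 in the main setting and 0.904 under median-of-ratios scaling, so the excess of higher regions may hang on the scaling. Its 2-fold counts under other scalings were not computed.

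No chromosome differed from the rest beyond counting error after adjustment. The lowest ratio with more than a few regions was on chromosome 3, at 0.928 (0.877 to 0.982) over 1214 regions (exact binomial p = 0.00963, Benjamini-Hochberg adjusted p = 0.202 over 21 chromosomes). The highest was on chromosome 10, at 1.05 (0.993 to 1.10) over 1242 regions. Chromosome X had a ratio of 0.996 (0.883 to 1.12) from 468 induced and 647 repressed counts. The 4 regions on chromosome Y held 3 and 7 counts, too few for a comparison.

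**Figure D3:**
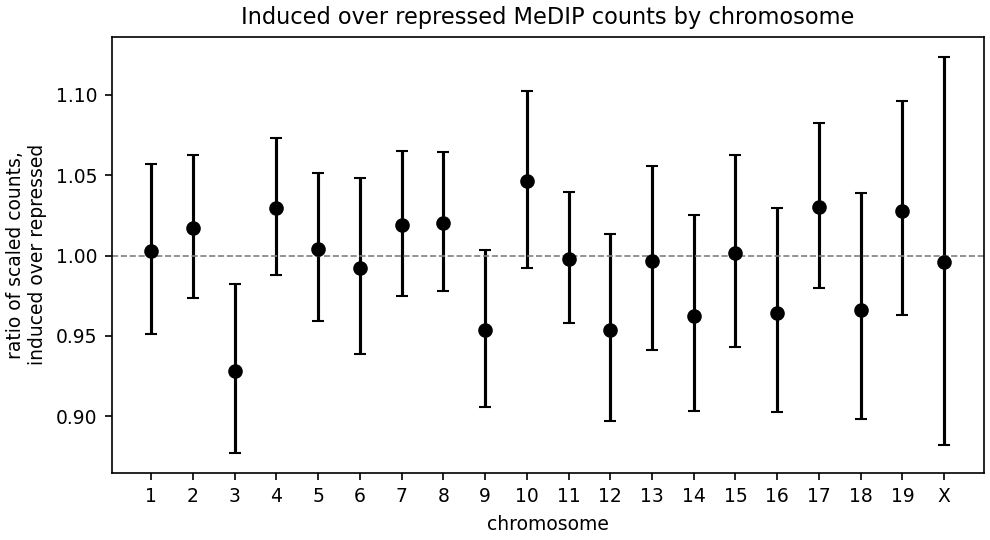
Induced-to-repressed ratio of summed scaled counts (vertical axis, not starting at 0) on each autosome and chromosome X (horizontal axis), with 95% exact binomial intervals as bars. Values lie between 0.928 on chromosome 3 and 1.05 on chromosome 10, and the interval excludes 1 on chromosome 3 alone.

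Among the scaled regions, the ratio near chromosome ends did not differ from the rest beyond counting error at any distance tried. The interval against the rest excluded 1 only when the 14 blank regions were included. Zscan4 has been studied for its part in telomere maintenance, and regions within 3 Mb of the outermost listed region of a chromosome were therefore compared with the others. The 1469 regions near either end had a ratio of 1.03 (0.987 to 1.08), and the other 22463 had 0.998 (0.986 to 1.01), so that the former was 1.04 times the latter (95% interval 0.988 to 1.09). Within 1 Mb the value lay on the other side of 1, though within counting error. There 520 regions, 47.1% of them lower and 39.4% higher, had a ratio of 0.963 (0.892 to 1.04). That ratio was 0.962 times that of the rest (0.891 to 1.04). Within 5 Mb it was 1.03 times that of the rest (0.996 to 1.08). At the start of the chromosome (within 3 Mb), which is the centromeric side in mouse, the ratio was 1.01 (0.944 to 1.08) over 824 regions. At the far end it was 1.06 (0.989 to 1.13) over 649 regions, 1.06 times that of the regions away from both ends (0.991 to 1.13). Of the 14 blank regions, 10 lie near an end and hold 1967 induced and 2551 repressed counts. With the blank regions included, the ratio within 3 Mb of either end was 1.04 (1.01 to 1.08), from 5098 and 6721 counts, and it was 1.05 times that of the rest (1.01 to 1.09). The 10 added regions form 5 loci when joined within 100 kb, and the 6 on chromosome X hold 2826 counts. These intervals cover counting error alone and take no account of so few loci. They do not show an effect at chromosome ends in general. Without the blank regions, 15.5% of regions within 3 Mb of the ends were lower and 16.3% higher by 2-fold or more, against 15.6% and 15.7% elsewhere. Telomere and satellite repeats themselves were not analysed here.

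In 1 Mb windows with at least 20 counts, 0 of 1316 passed the adjusted exact binomial test, and 95 had an unadjusted p under 0.05, against 56 in chance splits. The smallest adjusted p was 0.0877, for the window from 59 to 60 Mb on chromosome 13, with 68 induced and 43 repressed counts, which contains the called region R05912. The next window was lower in the induced library. It lay between 47 and 48 Mb on chromosome 18 and held 7 and 38 counts, a ratio of 0.254 (0.0956 to 0.575, adjusted exact binomial p = 0.140). Longer and shorter regions had similar values, with ratios of 1.01 (0.989 to 1.03) in regions of exactly 1000 bp and 1.00 (0.958 to 1.05) in regions of 2000 bp or more, the latter being 0.992 times the former (0.946 to 1.04).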

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

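All tests of explanations here were chosen after the patterns had been seen, and the simulation with the beta-binomial spread was added, with its bound, after the beta-binomial test itself was known to call no region.

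The 14 regions that the authors left without an adjusted value were set aside from the comparisons and form a signal outside the main measurement. They held 2456 counts in the induced library (4.80% of all) and 3137 in the repressed library (4.47%). Their summed counts, scaled by the factors of the other regions, gave a ratio of 1.08 (95% exact binomial interval 1.02 to 1.14), which became 1.03 (0.973 to 1.08) under TMM scaling and 0.895 (0.848 to 0.944) under the median of ratios. With scaling to equal totals, the ratio was above 1 in 8 of the 14, and the interval excluded 1 in 4, all above it: R01408 on chromosome 1 (197067420 to 197068420, 116 and 111 counts), R02654 on chromosome 11 (3092559 to 3094077, 405 and 468 counts), and R19016 and R19017 on chromosome 7 (7230473 to 7253370 together, 107 and 107, and 170 and 188 counts). Intervals of single blank regions were not computed under the other scalings, which lower all of these ratios. The intervals, single and summed, cover counting error alone, and no extra spread was applied to them. Scaled regions with 50 or more counts already spread by 2.71 times the binomial variance. These intervals may therefore be too narrow, and an interval without 1 is no sign of a difference beyond such spread. The 6 regions on chromosome X between 166423119 and 166445469 held 1215 and 1611 counts, a ratio of 1.04 (0.963 to 1.12).

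The induced-to-repressed ratio rose with the count of a region, from 0.931 at 1 or 2 counts to 1.09 at 20 or more. The 3 regions past the binomial test do not account for it, since without them the ratio at 20 or more counts was still 1.08 (1.05 to 1.11). Sorting regions on the same counts may favour chance highs of whichever library is noisier. When regions were instead sorted by the counts of their neighbours within 20 kb, the ratio of the upper tercile was 1.008 times that of the lower tercile (0.973 to 1.04). That interval holds both 1 and the 1.014 that the trend predicts, so this explanation and a true trend cannot be told apart with so few counts. The induced library also had 368 more regions without a count than the repressed library thinned to the same total (7247 against 6879), outside the range of −179 to 150 in chance splits. A difference in antibody enrichment or duplicate reads between the libraries and an effect of Zscan4 induction or of the absence of doxycycline stay open and untested, since each condition has 1 library.

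The 3 regions past the binomial test held 25 against 3, 30 against 6 and 50 against 18 counts. A beta-binomial test with the spread that all regions share called 0 of them. These calls ended because the spread widened what is expected of each region, while the ratios stayed at 11.5, 6.89 and 3.83. Lost calls alone do not favour this variation as the explanation, since that test recovered 7.5% of simulated 4-fold and 55.0% of 8-fold increases. Of 100 simulations with that spread and no other difference, 0 gave as many binomial calls, and the most in any was 2. The simulated spread, 0.0133, was fitted without these 3 regions and was 0.0165 with them. Leaving them out makes as many calls less likely in the simulations, so the test cannot decide whether variation that all regions share explains them. It also rests on an assumed form of that variation, a beta distribution, and a simulated setting excludes nothing, so the explanation stays open. A local gain of methylation in the induced cells is a possible explanation that these 2 libraries did not test, and a pile-up of duplicate reads at a single place is another.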

How the results depend on the processing

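Alternatives with no scaling, with the blank regions or with a minimum summed count, and all those of the binomial test, were chosen after seeing the data. Counts of regions past a fold threshold followed the settings for low counts. With a pseudocount of 10 there were 6 lower and 6 higher regions, and with 0.1 there were 6890 and 5350. At 1.5-fold 7522 were lower and 5969 higher, and at 3-fold 1347 and 1312. A mean signal at or above the median left 1824 and 1760, and a summed count of at least 20 left 30 and 43, since fewer regions were tested. Scaling changed the balance, with 4063 lower and 3387 higher under the median of ratios and 7537 and 3351 without scaling. The share of differing regions that were lower, 51.3%, was 53.1% under TMM, 55.4% under the median of ratios and 66.3% without scaling. It fell below 50% under filters: 45.9% at or above the median signal, 45.7% at or above the lowest quartile, and 42.5% at 20 or more counts. Both signal filters do so by construction, because an induced count weighs more in the scaled mean. The quartile filter keeps all 1402 regions with a single induced count and none of the 2181 with a single repressed count, and the median filter keeps all 876 with 2 induced and 1 repressed counts and none of the 1223 with the reverse. For the last filter the cause was not tested. The binomial test called 3 regions, and 3 under TMM, 0 with the beta-binomial spread, 0 under the median of ratios and 0 without scaling. The median of ratios is a coarse alternative at this depth, as stated above. The ratio near chromosome ends, 1.03, was 0.963 (0.892 to 1.04) within 1 Mb, and 1.10 at or above the median signal, where the other regions had 1.05. With the blank regions it was 1.04 (1.01 to 1.08). This interval, for counting error alone, excludes 1 because 10 regions with many counts join. The ratio of chromosome 3, 0.928, became 0.996 with the filter at the median signal, which raises ratios in general. Centring on the median ratio moved nothing, because that median was 0. No replicate could be left out, gene lists and promoter windows were not run, and at this depth 2.5% of simulated 2-fold and 90.0% of 8-fold increases were recovered among regions with 20 or more counts.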

Other observations

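The test of chromosome X below was chosen after its counts were seen; the values on chromosome 8 and at chromosome ends are descriptions without a test.

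Most chromosome X regions held few counts, while 6 regions at its far end held most of the counts of the chromosome. The median X region had a summed count of 1, against 3 on the autosomes. The 597 X regions with an adjusted value had 1.38 counts per kb over both libraries together (95% Poisson interval 1.30 to 1.47), against 3.69 on the autosomes, and this was 0.374 times the autosomal value in the induced and 0.375 times in the repressed library. The 6 blank X regions held 2826 counts, and with all blank regions included the order reversed: X had 4.84 counts per kb, above the highest autosome at 4.48. A measure that these 6 regions hardly move is the share of regions without a count, which was 32.0% of all 603 X regions (exact binomial interval 28.3 to 35.9) and 10.4% of autosomal ones. A single X copy, as in male cells, would be a candidate explanation. Thinning the autosomal counts by 0.5 gave 24.1% without a count, and between 21.1% and 28.6% on single autosomes, so the X interval reaches just into that range and the test leaves open whether 1 copy is enough. In counts per kb, the X regions with an adjusted value (1.38, upper end 1.47) lay below 0.5 times the lowest autosome (1.54). With the blank regions X lay above every autosome, so this measure does not settle it either. A lower methylation of the listed X regions, or a different kind of region listed on X, also stays open and was not tested.

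A cluster of 10 listed regions spans 236 kb on chromosome 8 (19784359 to 20020749) and includes 2 of the 14 regions with the highest counts and 2 of the 12 named lower regions. Its summed ratio was 1.03 (0.885 to 1.19) from 321 induced and 431 repressed counts, yet single members lay on both sides. R20688 held 28 and 16 counts, R20690 held 21 and 14, and R20697 held 23 and 14, each with an interval above 1, while R20689 held 4 and 17 and R20696 held 4 and 23, each with an interval below 1.

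Most of the regions with the highest counts lay near chromosome ends. No input library was analysed, so these counts cannot be read as methylation per copy of the sequence. Of the 14 regions without an adjusted value, 10 were within 3 Mb of the outermost listed region of their chromosome, against 6.14% of the other regions. Joined within 100 kb, the 14 regions form 7 loci, of which 5 lie near an end. With all listed regions, those within 3 Mb of the far end of a chromosome had 7.85 counts per kb over both libraries, those within 3 Mb of its start 4.63, and regions away from both ends 3.66. Without the blank regions the values were 4.37, 3.29 and 3.63, so the start then lay below the rest.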
